A study of Mus musculus with 8 samples.

How the data were processed

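Total RNA of mouse cells of the C57BL/6 strain was hybridised to 8 Affymetrix GeneChip arrays, in 4 groups of 2. Per the labels, the cells carried an empty vector, the full-length fusion NUP98-HOXA9, or a deletion mutant of the fusion named delFG1 or delFG2. NUP98-HOXA9 is a leukaemia fusion protein in which a part of the nucleoporin NUP98, rich in phenylalanine-glycine (FG) repeats, is joined to the DNA-binding homeodomain part of HOXA9. Which residues each deletion removes, the kind of cell, the species of the fusion cDNA and the array model are not given in the sources used here. Within each group the arrays carry the numbers 1 and 2 in the labels. Nothing in the labels says that the arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

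Per the labels' protocols, RNA was purified on RNeasy columns and the fragmented DNA made from it was biotin-labelled with a whole-transcript terminal labelling kit. The authors deposited 1 table of intensity values on a linear scale, with 28853 probe sets for each of the 8 arrays. How those values were background-corrected, summarised and normalised is not given in the sources used here. The values show that the arrays had been brought to nearly the same distribution: the largest gap between an array's sorted log2 values and the mean of all arrays lay between 0.03 and 0.07. No further normalisation was applied, and the values were analysed as log2(intensity + 1), on which scale all log2 differences and folds are given. The deposited table holds no background or detection calls, so low signals were kept, and the number of arrays limits the precision.

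Genes were named from the platform annotation supplied with the data, which lists 23410 probe sets. Of the probe sets in the table, 21789 carried 1 gene symbol and were tested, covering 19938 symbols; 1621 carried several symbols and 5443 none, and these entered no comparison. The Entrez gene numbers of 21698 tested probe sets were found in the RefSeq gene table of assembly GRCm38.p6, used for names only, and no symbol needed updating. No genomic coordinates are given, since no build is stated for the array. Each probe set was tested on its own, and the 999 genes with more than 1 probe set are named by the probe set with the highest mean over the 8 arrays.

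Differences were tested with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with an intensity trend, in a fit of all 8 arrays with the 4 group means and no further term. Residual degrees of freedom were 4, with 4.62 prior degrees of freedom. Benjamini-Hochberg adjustment ran over all tested probe sets in each of the 6 comparisons, with a threshold of 0.05. All p-values are two-sided. The order of comparisons was set before the data were examined: the full-length fusion against the empty vector, and each mutant against the full-length fusion, were the 3 main comparisons; each mutant against the empty vector and the mutants against each other were secondary.

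Since the numbers recur in every group, a second fit with the number as a block was planned, and whether the numbers pair the samples was checked first. The deviations of same-numbered arrays from their group means correlated across genes in all 6 pairs of groups, with r between 0.401 and 0.640. The numbers were therefore treated as pairing the samples; the pairing comes from the numbers in the labels and from these correlations, and what the numbers stand for is not stated. Results of the fit with the replicate block, which had 3 residual and 7.78 prior degrees of freedom, stand beside those of the fit without it wherever the call of a named gene, or of a gene list in a main comparison, differs.

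Genes to name were chosen by a rule fixed before the data were examined. For each main comparison it takes the 10 largest rises and 10 largest falls past the threshold whose arrays do not overlap between the groups, and for each secondary comparison 5 and 5. Free places go to the largest differences with an unadjusted p under 0.01, which are said not to have passed. Predicted genes, olfactory and vomeronasal receptors and small RNA genes are skipped in that ranking. Nup98, the Hoxa genes, Meis1, Pbx3, Mecom, Mycn, Cdk6, Flt3, Kit, Cd34, Mpo, Elane and Csf1r are always named, and each gene list gives up to 4 examples with the smallest p. Genes named outside this rule, from the fit with the replicate block, were chosen after their values were seen.

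For 25 gene lists fixed in advance, camera with an inter-gene correlation of 0.01 tested whether a list moved relative to other genes, and fry tested whether its genes moved one way on balance, with adjustment over the 25 lists. With an inter-gene correlation estimated from the data, camera called 0 lists in each of the 6 comparisons, so every camera call below depends on the preset value; at the preset value it called 12, 9 and 14 lists in the main comparisons. Counts of genes are given over all tested genes and adjusted over the list alone, the latter from the fit without the block unless the block is named. The share of the full-length effect that a mutant retained was measured on genes chosen in the arrays of 1 number, with a log2 difference of at least 1, and measured in the arrays of the other number, both ways. Correlations between comparisons that share arrays are set beside the mean of 100 simulations of unchanged groups.

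The calls of genes, the camera test and the retained shares were tested on simulated data made from the real means and spreads, for the full-length against the empty vector comparison with 21789 genes, of which 200 were changed. At 1.5-fold, 47.2% of changed genes were recovered without the block and 96.6% with it. At 2-fold these were 92.6% and 100%. The simulated arrays held the observed difference between the numbers and noise with the spread of the fit with the block. The gain in recovery with the block was therefore built in. False calls made up 0.0627% of calls without the block and 7.98% with it, which is above the share that a threshold of 0.05 allows, so calls that exist only with the block are less certain than their adjusted p. Retained shares of 90% and 50% came back as 90.1% and 50.2%. Camera called a planted list in 100% of simulations, but the simulated noise was independent between genes, so the preset inter-gene correlation was not tested. A count of genes that depart from a mixture of cells was simulated separately, with both mutants made as mixtures of full-length and empty vector intensities. Of 100 true mixtures, 18% gave 3 or more departing genes and 2% gave 5 or more. These were counted at the known share of 50%, while the count for the real data is the fewest over many shares. The simulated percentages therefore do not apply to that fewest count. On average 19.9 of 20 planted departing genes were found, with 4.69 others beside them. The random seed of these simulations was changed and their number raised from 10 after earlier results had been seen. No simulation tested fry or the comparison of the array numbers with the fusion's effect. Alternatives to the normalisation, the filter on dim probe sets, the variance model, the features tested, the threshold, the pseudocount of 1 (16 in its place) and the arrays in the fit were run, and each array was left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.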

Results

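Expression was compared between cells with an empty vector, the full-length NUP98-HOXA9 fusion and its deletion mutants delFG1 and delFG2, with 2 arrays in each of the 4 groups. The design asks which genes the fusion regulates through its NUP98 part. Median intensity was 80.7 to 83.2 in all 8 arrays and the lowest intensity of any array was 18.3. Arrays of a group correlated across genes with r between 0.995 and 0.996, and typically differed by 0.10 to 0.12 on the log2 scale. The highest correlation of any pair, 0.999, lay between arrays of different groups, the full-length and delFG1 arrays numbered 2.

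**Figure D1:**
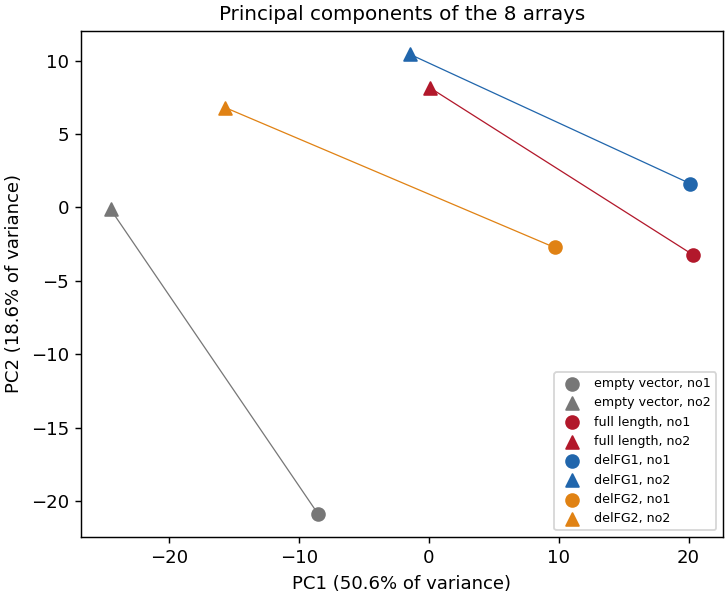
Principal components of log2(intensity + 1) over the tested probe sets, with 1 point per array, coloured by group and shaped by number, and a line joining the arrays of a group. Component 1 holds 50.6% and component 2 18.6% of the variance, and in each group the array numbered 2 lies to the left of and above the array numbered 1.

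Full-length NUP98-HOXA9 raised several genes of the Hoxa cluster together with partners of HOX proteins. Hoxa5, Hoxa6, Hoxa7 and Hoxa9, homeodomain transcription factors of blood progenitors, rose by 2.16, 2.26, 2.15 and 1.97 on the log2 scale, and Hoxa3 by 1.36. Eya1, a transcriptional coactivator and phosphatase, rose from 6.59 ± 0.23 to 9.02 ± 0.06 (SD, n = 2), a log2 difference of 2.43 with an adjusted p of 0.000761 by limma. Pbx3, which binds DNA together with HOX proteins, rose from 8.70 ± 0.07 to 10.44 ± 0.28, a log2 difference of 1.74 with an adjusted p of 0.00276. The largest rise was that of Csn2, the milk protein beta-casein, by 3.51 with an adjusted p of 0.00605, followed by the myosin light chain gene Myl10 by 2.51. Abcg3, an ABC transporter gene, rose by 2.13 and the endogenous retroviral gene Erv3 by 1.75.

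Genes that fell past the threshold, fewer than those that rose without the block and more with it, include products of mature myeloid cells and platelets. Stfa3, a stefin A inhibitor of cysteine proteases, fell by 2.73 with an adjusted p of 0.0182. Ppbp, a platelet chemokine, fell by 1.63, Anpep, the aminopeptidase CD13 of myeloid cells, by 1.08, Myof, a membrane repair protein, by 1.06, and Slc15a3, a lysosomal peptide transporter, by 0.97. With the replicate block, Mrgpra6 (-2.37), the stefin gene Stfa2 (-2.03), the fatty acid binding protein gene Fabp7 (-2.00), Acod1, whose product makes itaconate in macrophages (-1.98), and Slc6a12 (-1.53) fell as well. The stefin A genes are near-identical copies, so a signal cannot be assigned to a single copy with certainty.

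In all, 22 genes were higher and 5 lower with the full-length fusion than with the empty vector, of 21789 tested, and all 27 remained called with the replicate block, under which 475 were higher and 965 lower. Of these, 36 higher and 73 lower genes differed at least 2-fold. When each array was centred on its median, 26 genes were higher and 12 lower without the block. Leaving out 1 array at a time gave 7 genes (without the empty vector array numbered 1) to 36 (without either delFG2 array), and 385 (without the full-length array numbered 2) to 2378 (without the empty vector array numbered 2) with the block.

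Among the genes always named, Meis1, a homeodomain partner of HOX proteins, was higher by 0.80, Cd34, a surface marker of progenitors, by 0.86, Mycn by 0.50, Hoxa10 by 0.63 and Hoxa2 by 0.45, and Csf1r, the receptor of macrophage colony-stimulating factor, fell by 0.51. These 6 passed only with the replicate block. Nup98 itself (0.10), Cdk6 (0.09), Flt3 (0.50), Kit (-0.14), Mecom (0.20), Mpo (0.06), Elane (0.14), Hoxa4 (0.13), Hoxa11 (-0.01) and Hoxa13 (0.06) did not pass in either fit. Whether the Hoxa9 and Nup98 probe sets also read the introduced fusion is not known.

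**Figure D2:**
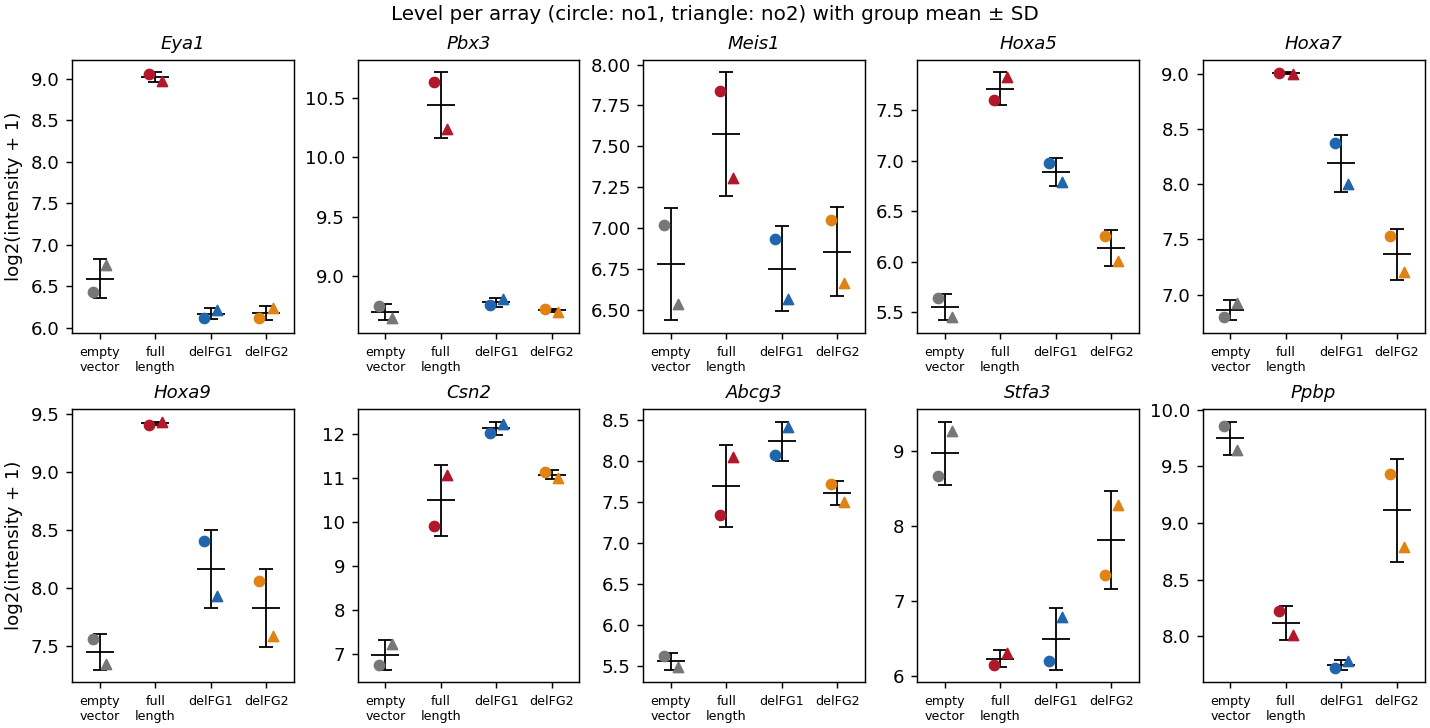
Log2(intensity + 1) of 10 named genes in each array (circles for number 1, triangles for number 2), with the group mean and SD (n = 2). Eya1, Pbx3 and Meis1 are high with the full-length fusion alone, the Hoxa genes lie between in the mutants, Csn2 and Abcg3 stay high in all 3 fusion groups, and Stfa3 and Ppbp are low with the full-length fusion and delFG1 and partly low with delFG2.

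By gene list, the Hoxa cluster led: 5 of 10 measured members rose (7 with the replicate block, and 7 adjusted over the list alone), with a mean difference of 1.04 between the arrays numbered 1 and 1.19 between those numbered 2. Its adjusted p was 7.93e-15 by camera, 0.204 with an estimated correlation and 0.00921 by fry. Of 27 members of the Hoxb, Hoxc and Hoxd clusters, Hoxc6 (1.06) and Hoxb5 (0.76) rose, 5 did with the block (among them Hoxb4 and Hoxc5) and 4 adjusted over the list alone (camera adjusted p = 0.00168, and adjusted p = 0.459 with an estimated correlation). Of 10 TALE homeobox cofactors, Pbx3 rose, Meis1 too with the block, and 2 passed adjusted over the list alone; camera gave no call (adjusted p = 0.163), and fry did (0.00921). Of 25 leukaemia self-renewal regulators, Eya1 rose, and with the block Mef2c (1.08), Mycn, Myc (0.36), Myb and Lmo2 rose and Id2 (-0.45) fell. In that list 3 genes passed adjusted over the list alone, with a camera adjusted p of 0.00912, and adjusted p = 0.459 with an estimated correlation. Of 22 stem and progenitor cell genes, Hoxb5 rose, 4 rose and 1 fell with the block, among them Cd34 and the angiopoietin gene Angpt1 (0.51), and 1 passed adjusted over the list alone (camera adjusted p = 0.185).

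Neutrophil, monocyte and inflammatory lists held genes that fell, none of which passed without the replicate block. Of 25 neutrophil granule and maturation genes, 0 passed by limma without the block. With it 11 fell, such as Olfm4 (-1.50), the chemokine receptor gene Cxcr2 (-1.09) and the integrin gene Itgam (-0.45). Gfi1 (0.81), a transcriptional repressor needed for granulocyte development, and Prtn3 rose with the block. The count adjusted over the list alone was 1 gene higher, and the camera adjusted p was 0.025 (3.31e-05 with the block), with adjusted p = 0.742 with an estimated correlation. In 23 monocyte and macrophage genes 0 passed without the block, and with it 12 fell, such as the mannose receptor gene Mrc1 (-1.15), the cathepsin gene Ctss (-0.82) and the Fc receptor gene Fcgr1 (-0.55), and the chemokine receptor gene Ccr2 (1.10) rose. For monocytes 1 was higher and 11 lower adjusted over the list alone, with a camera adjusted p of 4.69e-06 and adjusted p = 0.459 with an estimated correlation. Both lists also differed between the numbers: over all groups, 17 neutrophil and 10 monocyte genes were higher in the arrays numbered 2, with 1 of each lower. The same holds for 10 inflammatory, 7 mast cell and 5 eosinophil genes, with 1 mast cell gene lower. Of 25 inflammatory cytokines and receptors 0 passed without the block, and with it 9 fell, among them Il6 (-1.32), Il1a (-1.24) and Cxcl2 (-0.99), and 2 rose (Il10 and Vegfa). Of these genes 2 were higher and 5 lower adjusted over the list alone (camera adjusted p = 1.2e-05, and adjusted p = 0.459 with an estimated correlation).

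Mast cell, eosinophil, megakaryocyte and erythroid lists also held genes that fell, all but Ppbp with the block alone. Mast cell and basophil genes (20 measured) had 0 calls without the block and 2 higher and 6 lower with it, with the IgE receptor gene Fcer1a (-1.31) and the granzyme gene Gzmb (-0.84) lower and Ms4a2 (0.48) higher. Adjusted over the list alone 2 were higher and 5 lower (camera adjusted p = 9.96e-05, and adjusted p = 0.204 with an estimated correlation). Of 8 eosinophil genes 0 passed without the block or adjusted over the list alone, and 4 fell with it, such as Ear6 (-0.87) and Prg2 (-0.54), with a camera adjusted p of 0.00368 and adjusted p = 0.539 with an estimated correlation. Of 12 megakaryocyte genes, Ppbp fell, and with the block Vwf (-0.77), Itga2b and Pf4 (-0.49) fell and Gp9 rose. Adjusted over the list alone 1 was higher and 5 lower (camera adjusted p = 1.2e-05, and adjusted p = 0.204 with an estimated correlation). Of 16 erythroid genes 0 passed without the block; with it Rhag (-0.79) and Aqp1 (-0.58) fell and Car2 (0.78), a carbonic anhydrase, rose. Erythroid counts adjusted over the list alone were 1 higher and 3 lower, with a camera adjusted p of 0.00447, adjusted p = 0.204 with an estimated correlation and 0.0222 by fry.

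The cholesterol and nucleoporin lists were called by camera without any gene that passed in the fit without the block. Cholesterol synthesis genes (18 measured) had a mean difference of 0.21, 4 of them, with Sc5d (0.49) and Lss (0.39) first, rose with the block, and 1 passed adjusted over the list alone (camera adjusted p = 9.85e-05, and adjusted p = 0.459 with an estimated correlation). The 21 nucleoporins and nuclear export genes had a mean difference of 0.13 and 0 calls over all genes in either fit and 0 adjusted over the list alone without the block (2 higher with it); Rae1 (0.27) had the smallest p, with a camera adjusted p of 0.00875 and adjusted p = 0.742 with an estimated correlation. This list was also lower in the arrays numbered 2 in 13 of its 21 members.

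In the remaining lists 0 genes passed by limma without the block, and camera made no call. With the block, of 16 dendritic cell and MHC class II genes H2-DMa (0.61) and H2-Ab1 (0.74) rose, and camera then called the list (adjusted p = 0.0356, and 0.549 with an estimated correlation). Of 16 B lymphoid genes 3 fell with the block, the interleukin 7 receptor gene Il7r (-1.01) most; its median difference was 0.02 and its mean -0.08. Of 17 T and NK lymphoid genes Thy1 (0.59) rose. Of 15 stroma and endothelium genes Thbs1 (-0.49) fell and Lepr (0.46) rose, with a median and mean of 0.00 and -0.00. Of 32 cell cycle genes Ccnd1 (-0.55) and E2f2 (-0.49) fell, with a median of 0.03 and a mean of -0.02. Of 19 p53 targets and cell cycle inhibitors Sesn1 (0.64) rose and Perp (-0.60) fell. Of 26 interferon-stimulated genes Ifih1 and Bst2 rose and Cmpk2 fell, and of 25 MLL and associated chromatin complex genes Dpy30 (0.25) alone rose. Of 22 immediate-early genes Klf6 (-0.62), Egr2 and Fosl2 fell, where the list mean was 0.22 in the arrays numbered 1 and -0.41 in those numbered 2. Of 22 amino acid and unfolded protein response genes Asns, Aldh1l2 and Xbp1 rose and Slc7a11 (-0.93) and Slc3a2 fell, and of 19 glycolysis and hypoxia genes Vegfa rose and the glucose transporter gene Slc2a1 (-0.31) fell. Adjusted over the list alone and without the block, the counts higher and lower were 1 and 0 for dendritic cells, 0 and 3 for B cells, 0 and 0 for T cells, 1 and 1 for stroma, 0 and 0 for the cell cycle, 1 and 0 for p53 targets, 0 and 0 for interferon, MLL and immediate-early genes, 1 and 1 for amino acid genes, and 1 and 1 for glycolysis.

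With the block fry called 10 lists between full-length fusion and empty vector, in place of 3. The Hoxa cluster and the TALE cofactors had an adjusted p of 0.0258, the self-renewal, monocyte, eosinophil, erythroid and megakaryocyte lists 0.0373, the stem and progenitor cell and mast cell lists 0.0401, and the T and NK list 0.0464. Members that passed with the block include Mef2c, Mrc1 and Ear6.

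**Figure D3:**
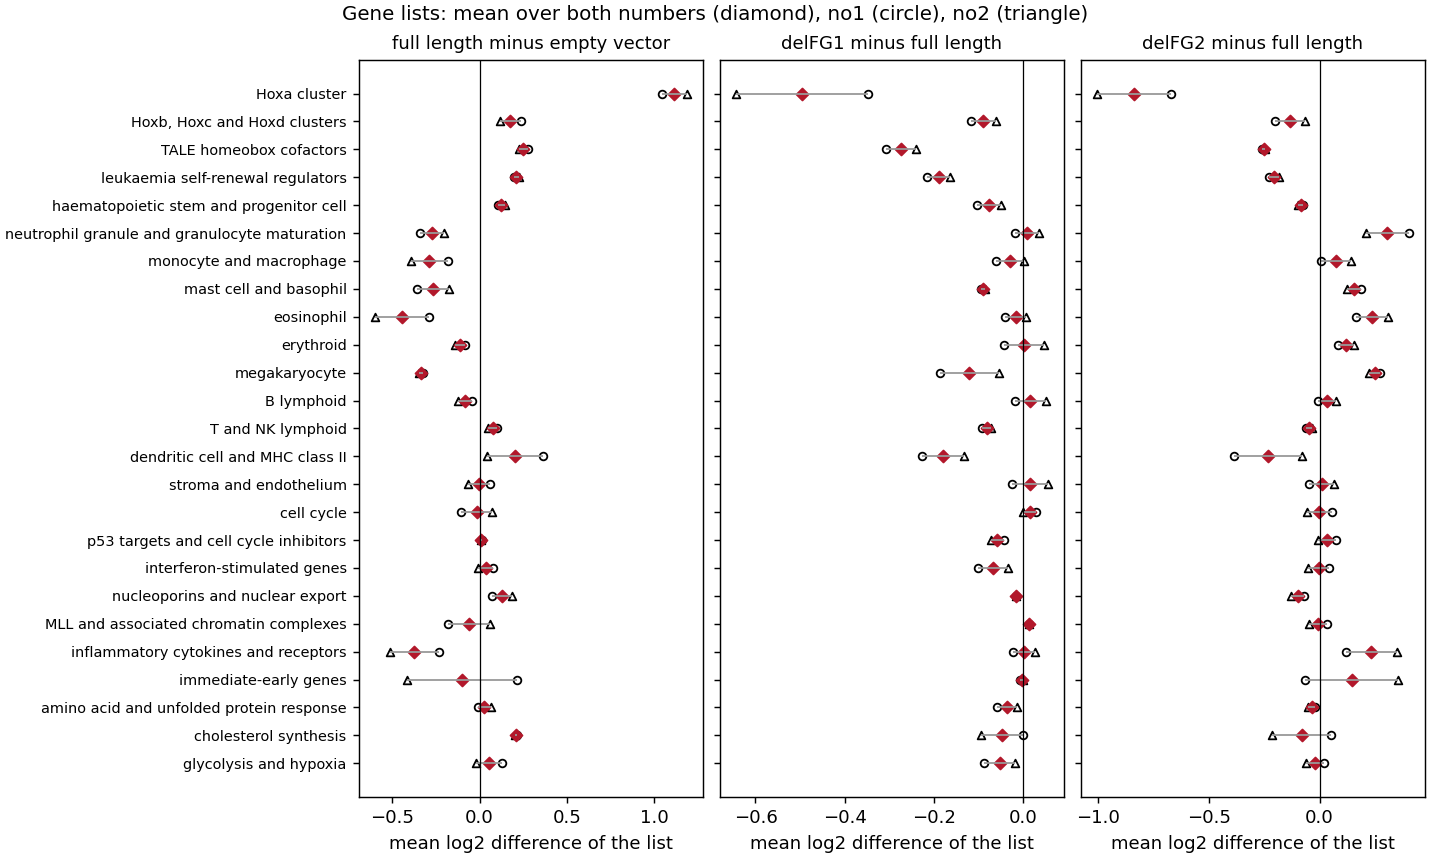
Mean log2 difference of each of the 25 gene lists in the 3 main comparisons, over all arrays (diamonds), within the arrays numbered 1 (circles) and within those numbered 2 (triangles). The Hoxa cluster is the list farthest from 0 in all 3 panels, up by a mean of 1.11 with the full-length fusion, and lower by -0.50 with delFG1 and -0.84 with delFG2 than with the full-length fusion.

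With delFG1 the rise of a small set of genes was lost or smaller, and most of the fusion's effect remained. Eya1 fell by 2.85 against the full-length fusion, to 6.17 ± 0.07 (SD, n = 2), with an adjusted p of 0.000196. Pbx3 fell by 1.66, to 8.78 ± 0.04, with an adjusted p of 0.0104. With the replicate block Hoxa9 (-1.25), Meis1 (-0.82), the transcription factor gene Mef2c (-0.79) and Calcrl (-1.07), the receptor of adrenomedullin, fell as well. Igfbp7 (-0.71), the Ras activator gene Rasgrp3 (-0.68), the casein gene Csn1s1 (-0.65), the ephrin receptor gene Epha3 (-0.63), Gm5662 (-0.62) and Hoxb5 (-0.62) completed the 12 genes lower with the block. Hoxa5 (-0.83) and Chil4 (2.42), a chitinase-like protein gene, just missed the threshold with the block, at an adjusted p of 0.0502 each, and Hoxa6 (-0.83), Hoxa7 (-0.82), Hoxa3 (-0.52) and Hoxa10 (-0.50) did not pass.

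A further set was higher with delFG1 than with the full-length fusion, in the fit with the replicate block alone. Tmem47, a membrane protein of cell junctions, was higher by 2.93 (block adjusted p = 0.00538), Csn2 by 1.64, the acyltransferase gene Glyat by 1.12, Tox, a nuclear factor of lymphocyte development, by 1.01, and the matrix protein gene Thbs4 by 0.93. The free places of the ranking went to Igf2r (1.22), the adhesion molecule gene Vcam1 (1.16), Gpx8 (0.94) and Prxl2a (0.74), and on the lower side to Crisp3 (-0.95) and P2rx3 (-0.93), none of which passed in either fit. A weaker probe set of P2rx3 gave -0.14. Nup98 (-0.05), Hoxa2 (-0.29), Hoxa4 (-0.01), Hoxa11 (0.05), Hoxa13 (0.04), Mecom (-0.33), Mycn (-0.03), Cdk6 (0.12), Flt3 (-0.30), Kit (0.08), Cd34 (-0.25), Mpo (-0.02), Elane (0.05) and Csf1r (0.02) did not pass either.

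Without the block, 0 genes were higher and 2 lower with delFG1 than with the full-length fusion by limma. In that fit 451 genes had an unadjusted p under 0.05, fewer than this threshold would give among 21789 unchanged genes. With the block 5 were higher and 12 lower. Leaving out 1 array gave 1 gene (without the full-length or the delFG1 array numbered 1, or either delFG2 array) to 4 (without the full-length or the delFG1 array numbered 2), and 5 to 44 with the block (lowest without the full-length array numbered 1, highest without the empty vector array numbered 2). Of 10 Hoxa genes 0 passed without the block, 1 with it and 7 adjusted over the list alone, all lower (camera adjusted p = 7.29e-15, and adjusted p = 0.234 with an estimated correlation). Of 10 TALE cofactors Pbx3 fell, Meis1 too with the block, and both adjusted over the list alone (camera adjusted p = 0.00216, adjusted p = 0.234 with an estimated correlation and 0.0298 by fry, the only list fry called here). Of 25 self-renewal regulators Eya1 fell, Mef2c too with the block, and 1 was higher and 3 lower adjusted over the list alone (camera adjusted p = 0.000736, and adjusted p = 0.411 with an estimated correlation). In the 25 neutrophil genes 0 passed in either fit or adjusted over the list alone, with a mean of 0.01, and likewise 0 of 23 monocyte genes, with a mean of -0.03.

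Camera called further lists after deleting FG1 in which few or no genes passed one by one, and none of them with an estimated correlation. Of 27 Hoxb, Hoxc and Hoxd genes 0 passed by limma, Hoxb5 fell with the block and 2 fell adjusted over the list alone (camera adjusted p = 0.00676, and adjusted p = 0.481 with an estimated correlation). Of 22 stem and progenitor cell genes Hoxb5 fell with the block, and 1 adjusted over the list alone (camera adjusted p = 0.0176, and adjusted p = 0.234 with an estimated correlation). Megakaryocyte genes, T and NK lymphoid genes, dendritic cell and MHC class II genes and interferon-stimulated genes had 0 calls over all genes in either fit and 0 adjusted over the list alone without the block (with it, 3 dendritic cell genes and 1 T and NK gene were lower). Their mean differences were -0.12, -0.08, -0.18 and -0.07, with camera adjusted p of 0.000736, 0.021, 0.000736 and 0.0302, and adjusted p = 0.234, 0.234, 0.411 and 0.481 with an estimated correlation. Mast cell and basophil genes were called by camera only with the block (adjusted p = 0.00454, and 0.347 with an estimated correlation), and the other lists were not called.

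Eya1, Pbx3 and Hoxa genes were lower with delFG2 than with the full-length fusion. Eya1 fell by 2.84 against the full-length fusion, to 6.18 ± 0.09 (SD, n = 2), with an adjusted p of 0.000199, and Pbx3 by 1.73, to 8.71 ± 0.01, with an adjusted p of 0.0074. Hoxa7 fell by 1.64, Hoxa5 by 1.58 with an adjusted p of 0.0114, Hoxc6 by 1.08 and Csn1s1 by 0.83. With the replicate block Hoxa9 (-1.60), Hoxa6 (-1.45), Hoxa3 (-1.11), Hoxa10 (-0.55), Meis1 (-0.72), Cd34 (-0.55), the inhibitory lymphocyte receptor gene Btla (-1.13) and Crisp3 (-1.19) fell as well, and Igfbp7 (-0.37), lower with delFG1, did not pass.

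Some genes of mature myeloid cells were higher with delFG2 than with the full-length fusion, again in the fit with the block alone. Of 23 monocyte and macrophage genes 1 rose with the block and 0 without it. Stfa3 was higher by 1.58, Stfa2 by 1.46, the resistin-like gene Retnlg of neutrophils by 1.44, Fcer1a by 0.86, Csta3 by 0.81 and Adgrl2, an adhesion receptor gene, by 0.67, and Ppbp rose 1.99-fold. All 8 probe sets of Adgrl2 were higher, by 0.22 to 0.71. Olfml2b (0.72), Egr1 (0.70) and Cxcl2 (0.67) held places in the ranking and did not pass in either fit. Nup98 (-0.08), Hoxa2 (-0.41), Hoxa4 (-0.10), Hoxa11 (0.04), Hoxa13 (-0.01), Mecom (-0.29), Mycn (-0.12), Cdk6 (-0.08), Flt3 (-0.45), Kit (0.06), Mpo (-0.05), Elane (-0.03) and Csf1r (0.08) did not pass either.

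Without the block, 0 genes were higher and 6 lower with delFG2 than with the full-length fusion by limma. In that fit 602 had an unadjusted p under 0.05, fewer than this threshold would give among 21789 unchanged genes. With the block 65 were higher and 37 lower. Leaving out 1 array gave 1 (without either delFG2 array) to 7 (without either delFG1 array), and 17 to 324 with the block (lowest without the delFG2 array numbered 1, highest without the empty vector array numbered 1). Of 10 Hoxa genes 2 fell, 6 with the block and 7 adjusted over the list alone, with a mean of -0.67 between arrays numbered 1 and -1.01 between those numbered 2 (camera adjusted p = 2.84e-20, adjusted p = 0.149 with an estimated correlation, and 0.016 by fry, which lost the call with the block at 0.0582). Of 10 TALE cofactors Pbx3 fell, Meis1 too with the block, and 1 passed adjusted over the list alone (camera adjusted p = 0.0221, adjusted p = 0.288 with an estimated correlation, and by fry 0.016, or 0.0464 with the block). Of 25 neutrophil genes 0 passed without the block or adjusted over the list alone, and 6 rose with the block (15 adjusted over the list alone), among them Mmp9 (1.03), Olfm4 (1.03), Cxcr2 (0.87) and the cathelicidin gene Camp (0.76), with a camera adjusted p of 7.9e-06 and adjusted p = 0.42 with an estimated correlation. Of 25 inflammatory genes 0 passed without the block or adjusted over the list alone, and Il6 (0.96) and Ccl6 (0.36) rose with the block (8 adjusted over the list alone; camera adjusted p = 0.000716, and adjusted p = 0.562 with an estimated correlation). Of 20 mast cell and basophil genes 0 passed without the block or adjusted over the list alone, and Fcer1a and Gzmb (0.75) rose with it (4 adjusted over the list alone; camera adjusted p = 0.000406, and adjusted p = 0.256 with an estimated correlation).

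Single genes of platelets, red cells and eosinophils were also higher with delFG2, in the fit with the block alone. Of 12 megakaryocyte genes 0 passed by limma without the block, Ppbp rose with it and 2 were higher adjusted over the list alone (camera adjusted p = 7.9e-06, and adjusted p = 0.187 with an estimated correlation). Of 16 erythroid genes 0 passed without the block, Rhag (0.59) rose with it and 2 were higher adjusted over the list alone (camera adjusted p = 0.00182, and adjusted p = 0.187 with an estimated correlation). Of 8 eosinophil genes Ear6 (0.56) alone rose, with the block (3 adjusted over the list alone; camera adjusted p = 0.0159, and adjusted p = 0.633 with an estimated correlation). Of 27 Hoxb, Hoxc and Hoxd genes Hoxc6 fell, Hoxb5 (-0.66) too with the block, and 3 adjusted over the list alone (camera adjusted p = 0.000764, and adjusted p = 0.396 with an estimated correlation). Of 25 self-renewal regulators Eya1 fell, Mef2c (-0.91) too with the block, and 3 adjusted over the list alone (camera adjusted p = 0.000406, and adjusted p = 0.336 with an estimated correlation). Dendritic cell, nucleoporin, immediate-early and cholesterol genes had 0 calls over all genes in either fit and 0 adjusted over the list alone without the block (with it, 1 dendritic cell gene higher and 6 lower), with mean differences of -0.23, -0.10, 0.15 and -0.08. Their camera adjusted p were 7.73e-05, 0.00182, 0.00506 and 0.0284, and adjusted p = 0.314, 0.646, 0.562 and 0.646 with an estimated correlation. The immediate-early and cholesterol means had opposite signs in the 2 numbers. With the block camera also called the stem and progenitor cell (adjusted p = 0.0292), monocyte (0.00392) and amino acid (0.0435) lists, and none of these with an estimated correlation.

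A small set of genes was lower in both mutants. Of 12 genes lower with delFG1 and 37 lower with delFG2 with the block, 11 were lower in both mutants than with the full-length fusion: Eya1, Pbx3, Hoxa9, Calcrl, Meis1, Mef2c, Rasgrp3, Csn1s1, Epha3, Gm5662 and Hoxb5. Independent lists would share 0.0204. All of these except Calcrl, 10 in number, were also higher with the full-length fusion than with the empty vector. Across genes, which are not independent replicates, the 2 effects correlated with r = 0.426, where unchanged groups that share the full-length arrays gave 0.50 in simulations, and their covariance exceeded the simulated one by 0.00187. Part of the overlap may come from the shared arrays, which were not split by number for this count.

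Against the empty vector, delFG1 kept much of the programme that the full-length fusion set. Csn2 rose by 5.15 with an adjusted p of 0.00202, Myl10 by 2.93, Abcg3 by 2.69, Mansc1 by 1.74 and Ccr4, a chemokine receptor of T cells, by 1.52. Hoxa6, Hoxa5 and Hoxa7 rose by 1.43, 1.33 and 1.33, and Hoxa9 (0.72), Hoxa3 (0.84), Cd34 (0.61), Mycn (0.47) and Elane (0.19) with the block. Stfa3 (-2.47), Ppbp (-2.00), Anpep (-1.07), and Myof (-1.03) fell, the ion channel gene Trpm2 fell 2.01-fold, and Csf1r (-0.49) with the block. Eya1 (-0.42), Pbx3 (0.08) and Meis1 (-0.03) did not pass. In all 19 genes were higher and 9 lower, and 422 and 911 with the block; the count of 28 went to 0 without the empty vector array numbered 1 and to 34 without either delFG2 array, and with the block lay between 487 (without the delFG1 array numbered 1) and 2272 (without the empty vector array numbered 2).

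Against the empty vector, delFG2 raised Csn2 by 4.09, with an adjusted p of 0.0136, as the only gene that passed without the block. With it Myl10 (2.26), Abcg3 (2.05) and the serpin gene Serpina3b (1.06) were higher, and Mrgpra6 (-1.45), Stfa3 (-1.15), Ralgds (-0.88), the interleukin 6 receptor gene Il6ra (-0.73) and the prostaglandin D synthase gene Hpgds (-0.73) were lower. Hoxa6 (0.81), Hoxa5 (0.58), Hoxa7 (0.51), Hoxa9 (0.37), Pbx3 (0.01), Meis1 (0.08), Eya1 (-0.42) and Retnlg (0.97) did not pass in either fit. The block gave 23 higher and 87 lower genes, and leaving out 1 array moved this from 2 (without the delFG2 array numbered 1) to 1065 (without the empty vector array numbered 2), and the count without the block from 0 (without the empty vector or the delFG2 array numbered 1) to 2 (without either full-length array).

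The effects of the 3 fusion forms against the empty vector resembled each other across genes. The full-length effect correlated with that of delFG1 at r = 0.868 and with that of delFG2 at 0.780, where unchanged groups sharing the empty vector arrays gave 0.50 in simulations of each pair. With the block, 257 genes were higher and 747 lower with both the full-length fusion and delFG1, where independent lists would share 9.20 and 40.3, and 19 and 86 with both the full-length fusion and delFG2 (0.501 and 3.85 if independent). The covariance exceeded the simulated one by 0.0350 and 0.0200, and part of the overlap may come from the shared arrays.

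delFG1 retained 91.3% of the full-length effect (87.5% and 95.1% in the 2 directions of the split) and delFG2 47.1% (38.1% and 56.0%), with no test; with the full-length arrays of the numbers crossed these were 214% and 121%. For delFG1 the share was 74.6% for genes higher and 100.5% for genes lower with the full-length fusion. On the linear scale these were 103% and 102%, and Csn2, which kept 355% on that scale, is among the higher genes. Hoxa5 kept 44.7% there, and how much Csn2 weighs in the 103% was not tested. Without Csn2 and the Hoxa cluster the shares on the log2 scale were 72.4% and 100.5%, and the cause of the gap was not tested. For delFG2 the share on the log2 scale was 44.2% for genes higher (27.0% and 61.4% in the 2 directions of the split) and 48.5% for genes lower. Gene by gene, Csn2 kept 149% with delFG1 and 119% with delFG2, Hoxa5 62.3% and 27.3%, Hoxa9 36.9% and 19.5% on the log2 scale, Pbx3 5.26% and 1.05%, and Eya1 -18.0% and -17.7%. Among genes lower with the full-length fusion, Stfa3 kept 90.9% and 42.9%, and Anpep 100.3% and 56.4%. On the linear scale Csn2 kept 355% and 174%, Hoxa5 44.7% and 14.8%, and Hoxa9 23.0% and 10.9%, so the size of these shares depends on the scale.

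**Figure D4:**
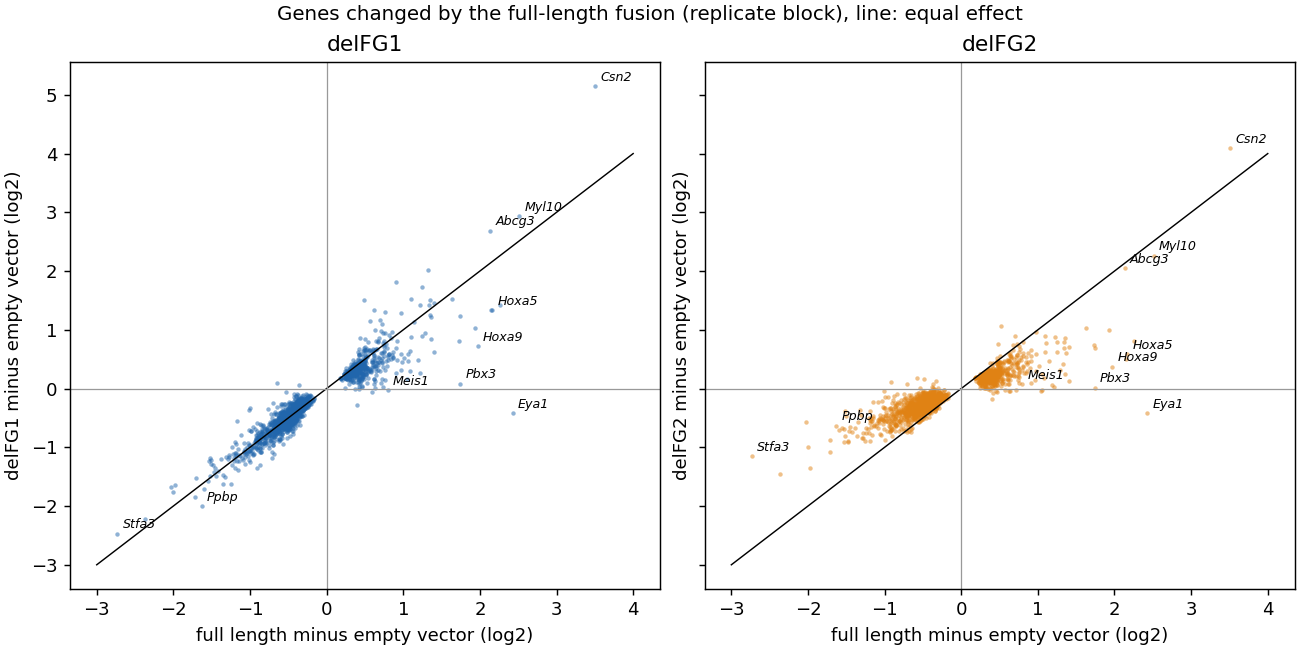
Log2 difference against the empty vector of the genes called with the replicate block between full-length fusion and empty vector, with the full-length effect on the horizontal axis and that of delFG1 (left) or delFG2 (right) on the vertical axis, 1 point per probe set. The line marks equal effects: with delFG1 most points lie along it and Eya1, Pbx3 and Meis1 lie near 0, while with delFG2 most points lie nearer 0 than the line and Csn2, Myl10 and Abcg3 lie close to it.

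The mutants differed from each other in single genes, with the replicate block alone. Ppbp was higher with delFG2 than with delFG1 by 1.36, Stfa3 by 1.32, Il6 by 1.15, Gzmb by 0.85 and Cstdc6 by 0.82. Tmem47 (-2.16), Hpgd, which breaks down prostaglandins (-1.59), the glutathione transferase gene Gstt1 (-1.25), Hoxa7 (-0.82) and Hoxa5 (-0.75) were lower. Chil4 (-1.76), Pfn2 (-1.24), Hoxa6 (-0.62), Hoxa3 (-0.59) and Hoxa9 (-0.34) did not pass, nor did Eya1, Pbx3 (-0.07) or Meis1 (0.11). Without the block 0 genes passed by limma. In that fit 683 had an unadjusted p under 0.05, fewer than this threshold would give among 21789 unchanged genes. With the block 88 were higher and 29 lower. Leaving out 1 array gave 0 genes without the block except for 4 without the delFG1 array numbered 2, and 1 to 313 with the block (lowest without the delFG1 array numbered 1, highest without the empty vector array numbered 1). Of 12 megakaryocyte genes 0 passed without the block, 2 were higher with it (Ppbp and Pf4), and 6 were higher adjusted over the list alone (camera adjusted p = 4.72e-12, and adjusted p = 0.14 with an estimated correlation). Mast cell genes had a mean of 0.25 (camera adjusted p = 8.02e-08, and adjusted p = 0.145 with an estimated correlation) and Hoxa genes -0.34 (3.8e-07, and 0.243 with an estimated correlation). Of 25 neutrophil and 23 monocyte genes 0 passed without the block, and 5 and 2 were higher with it (camera adjusted p = 0.000126 and 0.0402, and adjusted p = 0.755 and 0.895 with an estimated correlation).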

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

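The test of weaker repression in delFG2 was chosen after an earlier form of it had been seen, a partial correlation across genes of -0.684 against -0.500 in simulated unchanged groups, which was set aside because the difference between the numbers carries error of its own; its prediction was written before its own value, and the wording of the test on chance alignment was narrowed after its result was seen.

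Among the probe sets with several or no gene symbol, which entered no comparison, 1 without a symbol differed between full-length fusion and empty vector, and 175 of the 2 kinds did with the replicate block. With the block, the difference from the empty vector was itself different between delFG2 and delFG1 for 117 genes, tested as the contrast of the 2 mutants.

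Among these 117 genes are myeloid genes such as Ppbp and Stfa3, higher with delFG2 than with delFG1, and Hoxa5 and Hoxa7, lower, and the full-length effect runs against the difference between the array numbers across all genes (r = -0.498). Chance alignment of noise that is independent between genes is argued against, since 100 simulations of it gave -0.0166 to 0.0274, while noise shared between genes, such as a difference in maturity or handling between the numbers, stays open. A shift of the delFG2 arrays along this axis, as the whole account, was tested on 73 genes. They were lower with delFG1 than with the empty vector and not higher in the arrays numbered 2. With delFG2 they were higher than with the full-length fusion by a mean of 0.16 (SE 0.03 over genes, which are not independent), with 59 of 73 positive. For the 838 such genes higher in the arrays numbered 2 the mean was 0.24. The sorting used the number difference, whose error can misplace genes, so the 73 genes do not decide this. The measured Hoxa genes differed between the numbers by a mean log2 difference of -0.0660 and between delFG2 and the full-length fusion by -0.84, which argues against such a shift for them. A candidate explanation left open is the deletion itself, as a hypothesis, and a lower amount of the fusion protein in the delFG2 cells may give the same values, since that amount was not measured.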

How the results depend on the processing

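The replicate block combined with another setting or with an array left out, the retained shares on the linear scale, without the Hoxa cluster and on block-called genes were chosen only after the data were seen; the other settings were planned.

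With the replicate block, the counts of changed genes went from 27 to 1440 (full-length against empty vector), 2 to 17 (delFG1 against full-length), 6 to 102 (delFG2 against full-length), 28 to 1333 (delFG1 against empty vector), 1 to 110 (delFG2 against empty vector) and 0 to 117 (delFG2 against delFG1). In the same order, they were 1647, 9, 98, 1402, 193 and 148 with the block and the dimmer probe sets left out, and 109, 8, 20, 124, 6 and 14 with the block and at least a 2-fold difference. At an adjusted p under 0.1 without the block they were 68, 5, 10, 83, 3 and 1. Camera with the block called 13, 10, 17, 10, 5 and 10 lists, where it called 12, 9, 14, 8, 4 and 9 without, and fry 10, 1, 1, 2, 0 and 0, against 3, 1, 2, 2, 0 and 0. Among named genes and the gene lists of the main comparisons, the block changed no other call than those given beside each comparison. Leaving out the dimmer probe sets, those under the median, gave 17 genes for full-length against empty vector and 3 for delFG2 against full-length. Without the intensity trend the counts were 3 for delFG2 against full-length, 5 for delFG1 against empty vector and 0 for delFG2 against empty vector. In the last comparison 965 genes had an unadjusted p under 0.05 by limma with the trend. That is fewer than this threshold would give among 21789 unchanged genes. Array weights gave 5 for delFG1 against full-length. The weights were equal for the 2 arrays of each group, so this setting weighted groups and could not mark down a single array. The 2 groups alone gave 1 for delFG1 against full-length and 2 for delFG2 against empty vector. Testing every probe set gave 18 for delFG1 against empty vector. Fewer samples or more tests are part of these last settings, and for the others the cause was not tested.

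Leaving out 1 array gave 7 to 36, 1 to 4, 1 to 7, 0 to 34, 0 to 2 and 0 to 4 genes without the block, and 385 to 2378, 5 to 44, 17 to 324, 487 to 2272, 2 to 1065 and 1 to 313 with it; the lone array of a group is then taken to vary like the others. Without the block, the lowest counts for the full-length fusion and delFG1 against the empty vector came without the empty vector array numbered 1; several arrays share the lowest count in the other comparisons. Of 206 named results none reversed; of 38 that passed, 36 kept their call with quantile normalisation, 38 with median centring, 21 without the trend, 38 with the block and 11 to 31 with 1 array left out, the lowest without the empty vector array numbered 1. A reversal here means a change of sign with a call in either setting, so results uncalled in both may have changed sign. The retained share of delFG1 was 85.2% for genes chosen at a log2 difference of 2 and 74.9% for genes past the threshold. It was 74.6% for genes higher and 100.5% for genes lower with the full-length fusion, and 103% on the linear scale with Csn2 included. With the full-length arrays of the numbers crossed, it was 214%, and that of delFG2 121%, since crossing puts the difference between the numbers into the denominator. The lack of background readings limits what can be said of dim probe sets.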

Other observations

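The mixture tests were chosen only after the result was seen and were changed more than once. A form that argued against a mixture in both mutants made many false calls on simulated mixtures. The count of genes departing from a mixture, at the share with the fewest, was 17 for delFG1 and 3 for delFG2. Leaving out 1 array moved both counts down or up, depending on the array. The test on listed cell types was also chosen only after the result was seen.

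The arrays numbered 1 and 2 differed from each other in genes of mature myeloid cells and of nuclear pores, counted gene by gene, with no test of whole lists. With all groups in the fit, 2435 genes differed between the numbers, 1400 higher and 1035 lower in number 2. Of 25 neutrophil genes 17 were higher in number 2 and 1 lower; of 8 eosinophil genes 5, of 25 inflammatory genes 10 and of 19 p53 targets and cell cycle inhibitors 6. Of 21 nucleoporins 13 were lower in number 2, of 32 cell cycle genes 8 (and 2 higher) and of 25 self-renewal regulators 9 (and 1 higher). The 10 Hoxa genes had 0 calls by limma between the numbers. Of the 965 genes lower with the full-length fusion, 625 were higher in number 2 and 5 lower.

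Eya1, Pbx3, Meis1, Mef2c, Hoxa9 and 6 other genes, 11 in all, were lower in both mutants than with the full-length fusion. For all but Calcrl, which also passed as lower than the empty vector, a mixture of cells with and without the fusion's activity was considered. Eya1 (-0.42 with each mutant) and Rasgrp3 (-0.28 with delFG1 and -0.18 with delFG2) also lay below the empty vector, which a mixture does not give, but did not pass. A mixture gives all genes the same share of the full-length effect on the linear scale. With delFG1 the 10 genes without Calcrl kept a median of 6.08%. The 73 genes lower with the full-length fusion by at least 2-fold kept a median of 98.4%, and 95% of them kept 81.8% or more. The 10 genes had been chosen as lower with delFG1 on the same arrays, so their low share is partly fixed by that choice. In each number and with each array left out, the median of the 10 genes was at most 11.2% and the 5th percentile of the 73 genes at least 65.0%. These checks used the same 10 genes, so they cannot decide alone. The highest share among the 10 genes was 26.1%. Over all tested genes with the block, a share of 0.05 left 1241 genes departing from a mixture with delFG1, and 0.3 left 715. At a share of 1, which is no mixture, 17 departed. With the share of the 73 genes, which were not chosen by delFG1, these values argue against 1 shared mixture as the account of the 10 genes with delFG1. For delFG2 the medians were 8.24% and 59.6%, with the same choice of genes, and a mixture stays open there. The median of the 73 genes was 32.7% without the delFG2 array numbered 1 and 87.2% without the delFG2 array numbered 2. Without the empty vector array numbered 2, their 5th percentile fell to -31.1%, below the median of the 10 genes, then -2.11%. As a hypothesis, the 10 genes may need both the part deleted in delFG1 and the part deleted in delFG2. No test here decides this, and the amount of each fusion protein was not measured and stays open. Hoxa9 is among the 10 genes, and whether its probe set also reads the introduced fusion is not known.

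Tmem47, Csn2, Glyat, Tox and Thbs4 were higher with delFG1 than with both the full-length fusion and the empty vector, with the replicate block. For genes chosen by this pattern in 1 number, a single array as the cause is argued against. They were higher in the other number by a mean of 0.82 (15 of 15 genes) and 2.59 (4 of 4). These genes were chosen anew in each number and are not the named genes as such. Cells of another type stay open: the largest upward mean log2 shift of the 10 marker lists between delFG1 and the full-length fusion was 0.0167, over members that go both ways, which decides nothing. An activity gained by the deletion is a hypothesis that no test here separates from a difference between these cultures.

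Calcrl was lower in both mutants than in both other groups, by -0.89 with delFG1 and -0.72 with delFG2 against the empty vector. 1700001J11Rik was higher with delFG2 than with both other groups, by 0.42 against the full-length fusion and 0.38 against the empty vector. Both were seen with the replicate block alone and were chosen after their values were seen.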
